A study of Mus musculus with 35 samples.

How the data were processed

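Gene expression was measured with 1-color mouse oligonucleotide arrays in T cells and whole organs of healthy wild-type C57BL/6 female mice aged 8 to 16 weeks. Per the labels, liver, lungs and small intestine were dissociated, separated on a 40% and 80% Percoll gradient, and CD8+ resident memory T cells (Trm) were taken by 2 rounds of magnetic selection, on CD8b and then on CD103, the integrin chain that binds E-cadherin. Effector memory cells (Tem) came from the blood of the same animals as CD8b-positive cells after a further depletion step. Whole organs, which per the labels were not sorted after dissociation, and whole blood mononuclear cells (PBMC) served as controls for tissue cells left in the sorted samples. RNA with an integrity number above 8 was amplified in 2 rounds before labelling. There were 5 arrays of liver Trm, 6 each of lung Trm, intestine Trm and blood Tem, and 3 each of whole liver, whole lung, whole intestine and whole PBMC. The labels do not say which arrays came from which animal, so p-values measure the spread between these samples.

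The authors deposited scanner files whose values are an intensity, and a table of log2 values. Per the file headers, the intensity of each spot was background-subtracted and detrended, with low values replaced by a floor from an error model, by Feature Extraction version 11.0.1.1; the submitters' processing notes name version 10.7 and Partek. The deposited log2 values matched a quantile normalization of those intensities over all 35 arrays (largest median absolute difference over arrays 0.000515). Each array held 43020 spots for 39429 probes, 399 of which were printed 10 times and averaged. Probe accessions were looked up in a RefSeq gene table for GRCm38.p6, which named 27508 probes of 20886 genes and left 11921 probes without a name. Itgae, which encodes CD103, and Zfp683 had no probe matched to them, and Itga1 did not pass the filter among the sorted cells.

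For the main results, log2 intensities were scaled by subtracting the 75th percentile of each array, taken over the probes that the scanner software marked well above background on every array of a fit (4042 probes for the sorted cells and 1341 for all arrays). A probe was kept when it was well above background on at least 3 arrays of a group, and each gene was represented by its probe with the highest mean. limma 3.58.1 in R 4.3.3 was fitted to 8621 genes on the 23 sorted-cell arrays, with one mean per group, for the comparisons among Trm populations and Tem, and to 10635 genes on all 35 arrays for the comparisons with whole organs. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Lists of genes were tested with camera from limma at a preset correlation of 0.01, over 30 lists in 6 comparisons (180 tests adjusted together), and again with a correlation estimated from the data. The lists, the comparisons, the tests and most of the alternatives were fixed before the data were examined. Lists overlap, and the marker lists of other cell types are textbook markers that T cells can also express in part. Random regroupings of the 23 sorted-cell arrays gave a median of 49 list calls at the preset correlation. Adjusted p-values at that correlation therefore overstate the evidence, and a list call that rests on it alone does not establish a shift.

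The genes named were chosen by rule. They are the 8 called genes with the largest fitted difference in each direction, among genes with an official symbol that were well above background on every array of the brighter group, the 4 called members with the largest fitted difference from each list described, and 18 genes of T cell sorting, homing and function. A gene with no probe well above background on any array of the dimmer group has a fold given as a lower bound, from the mean of the brighter group against the lowest signal that was well above background on each dimmer array, or the gene's own signal where that was higher. Genes called in the same direction in all 3 comparisons with Tem were counted and set beside 100 simulations of unchanged groups and beside splits of the Tem arrays. Genes specific to 1 Trm population were those called against Tem and against both other Trm populations in the same direction. Whole-organ genes were the 50 called genes with the largest difference between a whole organ and whole PBMC.

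The alternatives were quantile normalization, background correction by normexp with an offset of 50, the deposited log2 values, no filter and a stricter filter on dim probes, a minimum of 2-fold, the mean of all probes of a gene, array weights, a fit of only the 2 groups compared, the slide as a block, and leaving out each array in turn. Normexp was run on the median spot and background columns in place of the mean spot column that had been planned, which the scanner files lack. Scaling over all probes and leaving out 4 doubted arrays were added later. The arrays sat on 9 slides: the sorted cells on 6, each holding up to 1 array of each sorted group, and the whole organs on the other 3, which were scanned in another session. The slide and the replicate number coincide for the sorted cells. No spot was saturated, and the number of arrays limits the precision. The tests were also run on simulated data in which 50 genes were changed at each of several sizes. Of 4-fold changes, 84% were recovered for liver Trm against Tem, 76% for lung Trm and 56% for intestine Trm. Of 2-fold changes the shares were 20%, 16% and 26%. Each share comes from a single draw of 50 genes simulated independently of each other. Differences in these shares between populations therefore do not show a difference in power. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.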

Results

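The 35 arrays measured 8 groups of samples from mouse liver, lung, small intestine and blood. Trm cells of liver (n = 5), lung (n = 6) and intestine (n = 6) were compared with blood Tem (n = 6) and with each other. Each sorted population was also set against its whole organ, or whole PBMC for Tem (n = 3 each). Among the sorted cells, 12.2% to 35.5% of probes were well above background per array. Group means were 21.9% in liver Trm, 28.4% in lung Trm, 26.3% in intestine Trm and 29.4% in Tem. Whole organs and PBMC ranged from 7.80% to 64.6%. Replicates of a sorted group had rank correlations across probes of 0.793 to 0.937, and probes are not independent replicates. The lowest correlation within whole PBMC was 0.473. The first component of the sorted cells carried 33.6% of the variance and set liver Trm 3, 5 and 6 apart from liver Trm 1 and 2.

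**Figure D1:**
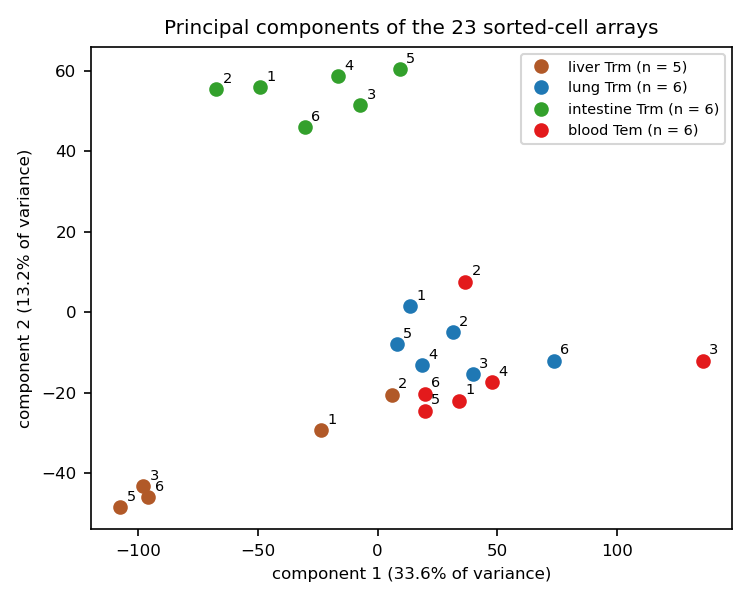
First and second principal components of the scaled log2 signal of the 23 sorted-cell arrays, each point 1 array, colored by group and numbered by replicate. Intestine Trm lies apart from the other groups on component 2 (13.2% of variance), and Tem 3 and liver Trm 3, 5 and 6 lie at opposite ends of component 1 (33.6% of variance).

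Liver Trm against blood Tem asked which genes mark CD103-selected cells of the liver. Each gene is given with its log2 difference ± SE and its adjusted p from limma. Its direction was the same on every slide holding both groups unless a number of slides is given. Cx3cr1, the fractalkine receptor (-5.51 ± 0.89, adjusted p = 2.2e-04, at least 13.1-fold lower), and Klrg1, an inhibitory receptor of effector cells (-4.87 ± 0.60, adjusted p = 8.0e-06, at least 6.49-fold lower), were among the circulation-associated genes that fell in liver Trm. Of 27 such genes, 15 fell, 1 rose and 11 did not pass, with 18 called when adjusted over the list alone. Here and below, a count adjusted over the list alone holds calls in both directions. As a list they shifted down (median -1.18, adjusted p = 0.00407; adjusted p = 0.205 with an estimated correlation). Among cytotoxic effector genes, 11 of 18 fell and 2 rose, with 14 called when adjusted over the list alone. Gzmb, which encodes granzyme B (-3.64 ± 0.96, adjusted p = 0.00785), and Gzma (-2.41 ± 0.60, adjusted p = 0.00593) fell. So did Gzmm (-2.83 ± 0.40, adjusted p = 5.2e-05) and Serpinb6b, a serine protease inhibitor (-3.43 ± 0.58, adjusted p = 3.5e-04). The cytotoxic list shifted down (median -1.15, adjusted p = 0.0379; adjusted p = 0.605 with an estimated correlation). That shift was not called under quantile normalization, with the deposited values, with scaling over all probes or without liver Trm 3 and Tem 3. Leaving out liver Trm 1, 2 or 5 or Tem 2 or 3 also ended it (highest adjusted p 0.0750).

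Genes of proliferation fell in liver Trm, 16 of 23, with 19 adjusted over the list alone (median -1.37, adjusted p = 1.7e-04; adjusted p = 0.626 with an estimated correlation). They included the cyclin gene Ccna2 (-3.33 ± 0.81, adjusted p = 0.00496, at least 3.31-fold lower) and Cdc20, an activator of the anaphase-promoting complex (-3.12 ± 0.81, adjusted p = 0.00746). The chemokine receptor gene Cxcr3 (-3.48 ± 0.61, adjusted p = 5.0e-04) and the cytokine gene Il16 (-3.42 ± 0.41, adjusted p = 4.5e-06) also fell. Immediate early and stress genes rose, 21 of 36, with 22 adjusted over the list alone (median 1.35, adjusted p = 3.3e-09; adjusted p = 0.170 with an estimated correlation). Egr2, a transcription factor induced by receptor signals (3.82 ± 0.62, adjusted p = 2.5e-04, at least 3.06-fold higher), and Gadd45g (3.98 ± 0.88, adjusted p = 0.00313) were among them. The metallothionein gene Mt2 rose as well (4.93 ± 0.94, adjusted p = 0.00106). Residency-associated genes went both ways, 5 higher and 7 lower of 37, with 10 adjusted over the list alone. No shift of that list was called (median 0.21, adjusted p = 0.244). The sort marker Cd8b1 was lower (-1.17 ± 0.34, adjusted p = 0.0126). Cd69, a marker of recent activation and of residency, was not called (0.79 ± 0.43, adjusted p = 0.136, 4 of 5 slides). Neither were S1pr1 (-0.14 ± 0.42, adjusted p = 0.795, 3 of 5 slides) and Klf2, which drives transcription of S1pr1 (0.57 ± 0.27, adjusted p = 0.0934).

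The chemokine receptor gene Cxcr6 fell in liver Trm (-1.32 ± 0.44, adjusted p = 0.0224). That call did not hold without liver Trm 3, 5 or 6 or Tem 2 (highest adjusted p 0.0799). Hepatocyte markers rose in 21 of 22, with 21 adjusted over the list alone (median 6.19, adjusted p = 1.0e-26; adjusted p = 0.0839 with an estimated correlation). Alb, which encodes serum albumin (8.51 ± 0.60, adjusted p = 1.3e-09, at least 87.5-fold higher), and Ahsg, a plasma glycoprotein (9.27 ± 0.56, adjusted p = 1.8e-10, at least 164-fold higher), were among them. Relative to whole liver, Alb lay at -1.86 (adjusted p = 0.0685) and Ahsg at -0.82 (adjusted p = 0.346). Serpina1c rose as well (9.92 ± 0.57, adjusted p = 1.5e-10, at least 201-fold higher), and its probe can also bind transcripts of its paralogs. Liver endothelial and Kupffer cell markers rose in 10 of 11, with 10 adjusted over the list alone (median 2.95, adjusted p = 1.0e-09; adjusted p = 0.107 with an estimated correlation). Clec4g (7.55 ± 0.50, adjusted p = 5.4e-10, at least 43.1-fold higher) and Stab2 (6.14 ± 0.46, adjusted p = 3.6e-09, at least 15.6-fold higher), receptors of sinusoidal endothelium, were among them. Neutrophil and mast cell markers rose in 7 of 9, with 7 adjusted over the list alone (median 2.93, adjusted p = 2.1e-04; adjusted p = 0.210 with an estimated correlation), including S100a8 (4.68 ± 0.94, adjusted p = 0.00158).

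Probes never above background were 1.33 higher in liver Trm than in blood Tem (log2 median). Of the list medians that follow, those of the enterocyte and Paneth cell lists equalled that value. The fibroblast, lung epithelial and monocyte medians lay near it. Those shifts cannot be told apart from a difference in background. Lung endothelial and stromal markers in liver Trm rose in 7 of 18, with 8 adjusted over the list alone (median 1.80, adjusted p = 9.9e-05; adjusted p = 0.438 with an estimated correlation). Enterocyte and gut epithelial markers rose in 5 of 14, with 5 adjusted over the list alone (median 1.33, adjusted p = 6.5e-04, 4 of 5 slides; adjusted p = 0.458 with an estimated correlation). Fibroblast and smooth muscle markers rose in 4 of 12, with 3 adjusted over the list alone (median 1.54, adjusted p = 0.00402, 4 of 5 slides; adjusted p = 0.599 with an estimated correlation), a shift not called with normexp. Lung epithelial markers rose in 3 of 14, with 3 adjusted over the list alone (median 1.42, adjusted p = 0.0145, 4 of 5 slides; adjusted p = 0.675 with an estimated correlation), a shift also not called with normexp. Paneth, goblet and enteroendocrine markers rose in 2 of 10, with 2 adjusted over the list alone (median 1.33, adjusted p = 0.00715, 4 of 5 slides; adjusted p = 0.571 with an estimated correlation), a shift not called under quantile normalization or with the deposited values. Monocyte, macrophage and dendritic cell markers rose in 4 of 18, with 5 adjusted over the list alone (median 1.18, adjusted p = 0.0436; adjusted p = 0.659 with an estimated correlation) and fell in 1. That shift ended under quantile normalization, with the deposited values, with normexp, and without liver Trm 2, intestine Trm 2 or 3 or Tem 1, 2, 4 or 6 (highest adjusted p 0.0789).

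In liver Trm 1288 genes were higher than in Tem and 2189 lower, 3477 of 8621 tested. With the slide as a block there were 3062 calls, and 2346 of the calls had one direction on all 5 shared slides. Of the higher genes 396 of 1288, and of the lower genes 2016 of 2189, were above background on every array of the brighter group. The split was 1959 higher and 993 lower with normexp, and 965 higher and 3898 lower with scaling over all probes. The count was 2242 without liver Trm 6 and 1774 without the doubted arrays liver Trm 3 and Tem 3.

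Cx3cr1 (-5.43 ± 0.85, adjusted p = 3.8e-04), Klrg1 (-5.94 ± 0.58, adjusted p = 3.5e-06, at least 13.9-fold lower) and S1pr5, a sphingosine 1-phosphate receptor (-3.35 ± 0.46, adjusted p = 1.1e-04, at least 2.06-fold lower), were lower in lung Trm than in blood Tem. Gzmb (-4.89 ± 0.91, adjusted p = 0.00280) and Gzma (-3.81 ± 0.57, adjusted p = 2.7e-04) were lower too. Fasl, the ligand of the death receptor Fas, fell as well (-3.30 ± 0.73, adjusted p = 0.0113, 5 of 6 slides). Sftpc, a surfactant gene of alveolar epithelium (6.22 ± 0.90, adjusted p = 1.8e-04), and Chil3, a chitinase-like protein of alveolar macrophages (7.41 ± 0.75, adjusted p = 3.7e-06), rose. The ribonuclease gene Ear2 rose with them (6.20 ± 0.64, adjusted p = 3.9e-06).

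Circulation-associated genes fell in 6 of 27 in lung Trm and none rose, with 14 adjusted over the list alone. The list shifted down (median -0.71, adjusted p = 5.6e-09), also with an estimated correlation (adjusted p = 0.0273). Homing and adhesion receptors fell in 5 of 24, including Cxcr3 (-3.64 ± 0.58, adjusted p = 4.9e-04). Adjusted over the list alone 8 were called, 7 lower and 1 higher. Their shift (median -0.41, adjusted p = 1.5e-04) was also called with an estimated correlation (adjusted p = 0.0273). Cytotoxic effector genes fell in 5 of 18, with 12 adjusted over the list alone, 11 lower and 1 higher (median -1.26, adjusted p = 1.0e-06; adjusted p = 0.137 with an estimated correlation). Immediate early genes rose in 12 of 36, with 19 adjusted over the list alone (median 1.21, adjusted p = 6.7e-20; adjusted p = 0.0612 with an estimated correlation). Fosb, a subunit of the AP-1 transcription factor (4.59 ± 0.67, adjusted p = 2.0e-04), Klf4 (4.86 ± 0.52, adjusted p = 6.2e-06, at least 9.27-fold higher) and Egr2 (4.59 ± 0.60, adjusted p = 5.9e-05, at least 5.20-fold higher) were among them. No proliferation gene was called, 0 adjusted over the list alone, while the list of 23 shifted down (median -0.96, adjusted p = 2.6e-05, 5 of 6 slides; adjusted p = 0.571 with an estimated correlation). Residency-associated genes rose in 2 and fell in 2 of 37, with 6 adjusted over the list alone (median -0.16, adjusted p = 0.850). Runx3, a transcription factor of CD8 T cells, fell (-2.07 ± 0.45, adjusted p = 0.00943). Cd8b1 (-0.26 ± 0.33, adjusted p = 0.743, 5 of 6 slides) and Cxcr6 (-0.38 ± 0.42, adjusted p = 0.705, 4 of 6 slides) were not called.

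Cd69 rose in lung Trm (1.54 ± 0.41, adjusted p = 0.0364, 5 of 6 slides). That call ended with the slide as a block, with scaling over all probes, and without lung Trm 2, 3, 5 or 6 or Tem 3, 4, 5 or 6 (highest adjusted p 0.0857). Tbx21, which encodes T-bet, fell (-1.83 ± 0.48, adjusted p = 0.0364, 5 of 6 slides). Its call ended with the slide as a block and without lung Trm 1, 2 or 3 or Tem 1, 2, 4, 5 or 6 (highest adjusted p 0.0783). Lung epithelial markers rose in 6 of 14, with 10 adjusted over the list alone (median 4.39, adjusted p = 4.6e-16, 5 of 6 slides; adjusted p = 0.0839 with an estimated correlation). Monocyte, macrophage and dendritic cell markers rose in 7 of 18, with 9 adjusted over the list alone (median 1.66, adjusted p = 6.4e-10; adjusted p = 0.0839 with an estimated correlation). Neutrophil and mast cell markers rose in 4 of 9, with 6 adjusted over the list alone (median 1.72, adjusted p = 1.4e-07; adjusted p = 0.0839 with an estimated correlation), including S100a9 (6.83 ± 1.06, adjusted p = 3.7e-04). Against whole lung, Chil3 lay at 0.95 (adjusted p = 0.416) and Sftpc at -1.69 (adjusted p = 0.153). In lung Trm 181 genes were higher than in Tem and 89 lower, 270 in all, and 175 without lung Trm 2. With the slide as a block there were 233, and 223 of the calls had one direction on all 6 slides.

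Lung endothelial and stromal markers in lung Trm rose in 1 of 18, with 6 adjusted over the list alone (median 1.91, adjusted p = 4.1e-07, 5 of 6 slides; adjusted p = 0.285 with an estimated correlation). Liver endothelial and Kupffer cell markers rose in 1 of 11, with 1 adjusted over the list alone (median 0.39, adjusted p = 0.00402, 4 of 6 slides; adjusted p = 0.480 with an estimated correlation). Hepatocyte markers rose in 2 of 22, with 2 adjusted over the list alone (median 0.25, adjusted p = 0.0192, 3 of 6 slides; adjusted p = 0.790 with an estimated correlation). Enterocyte and gut epithelial markers rose in 1 of 14, with 1 adjusted over the list alone (median 0.27, adjusted p = 0.0145, 4 of 6 slides; adjusted p = 0.662 with an estimated correlation). Paneth, goblet and enteroendocrine markers rose in 1 of 10, with 2 adjusted over the list alone (median 0.38, adjusted p = 0.0145, 4 of 6 slides; adjusted p = 0.626 with an estimated correlation). No fibroblast or smooth muscle marker was called, 0 adjusted over the list alone (median 0.55, adjusted p = 0.0192, 5 of 6 slides; adjusted p = 0.675 with an estimated correlation). The shifts of the last 4 lists ended under quantile normalization, with the deposited values and without liver Trm 3 and Tem 3, and that of hepatocyte markers also with normexp. Without Tem 3 alone, hepatocyte, enterocyte and Paneth cell markers were not called, nor hepatocyte markers without lung Trm 5 (highest adjusted p 0.110, 0.104 and 0.0662). Probes never above background were 0.24 higher in lung Trm than in blood Tem (log2 median). The hepatocyte and enterocyte medians lay at that level, and the Paneth cell and liver endothelial medians close to it. Those shifts cannot be told apart from a difference in background.

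P2rx7, an ATP-gated channel (4.24 ± 0.66, adjusted p = 1.3e-04), and Litaf (4.04 ± 0.46, adjusted p = 2.2e-06) were among the residency-associated genes that rose in intestine Trm compared with blood Tem. Ahr, the aryl hydrocarbon receptor (3.84 ± 0.59, adjusted p = 1.0e-04), and the transcription factor gene Bhlhe40 (3.46 ± 0.64, adjusted p = 6.8e-04) rose as well. Of 37 such genes 20 rose and none fell, with 25 in either direction adjusted over the list alone (median 1.62, adjusted p = 5.9e-11; adjusted p = 0.0873 with an estimated correlation). S100a4, a calcium-binding protein (-5.49 ± 0.60, adjusted p = 1.3e-06), Cx3cr1 (-4.72 ± 0.85, adjusted p = 5.3e-04) and Klrg1 (-3.92 ± 0.58, adjusted p = 6.5e-05) fell. Circulation-associated genes fell in 17 of 27, with 22 in either direction adjusted over the list alone. That shift (median -1.57, adjusted p = 9.7e-11) was also called with an estimated correlation (adjusted p = 0.0210). Naive and central memory genes fell in 13 of 29 and rose in 1, with 17 adjusted over the list alone (median -0.96, adjusted p = 7.3e-05, 5 of 6 slides; adjusted p = 0.438 with an estimated correlation). Dapl1 (-4.22 ± 0.73, adjusted p = 3.6e-04, 5 of 6 slides) and Bach2, a transcriptional repressor (-2.80 ± 0.49, adjusted p = 4.6e-04), were among those that fell.

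S1pr1 (-1.79 ± 0.40, adjusted p = 0.00339, 5 of 6 slides) and Cd8b1 (-1.21 ± 0.33, adjusted p = 0.0132) fell in intestine Trm, and Cd69 rose (1.76 ± 0.41, adjusted p = 0.00442). Ccr7 (-0.22 ± 0.35, adjusted p = 0.674, 5 of 6 slides), Klf2 (-0.67 ± 0.26, adjusted p = 0.0761, 5 of 6 slides) and Cxcr6 (0.27 ± 0.42, adjusted p = 0.678, 5 of 6 slides) were not called. Activation and checkpoint receptors rose in 6 of 18, with 8 in either direction adjusted over the list alone (median 0.72, adjusted p = 0.00179, 5 of 6 slides; adjusted p = 0.389 with an estimated correlation). Pdcd1lg2, a ligand of PD-1 (3.45 ± 0.57, adjusted p = 2.4e-04, at least 2.44-fold higher), and the inhibitory receptor gene Ctla4 (2.78 ± 0.48, adjusted p = 3.5e-04, 5 of 6 slides) were among them. No shift of cytotoxic effector genes was called, 2 higher and 1 lower of 18, with 3 adjusted over the list alone (median 0.32, adjusted p = 0.254). The chemokine gene Ccl4 rose (2.70 ± 0.50, adjusted p = 7.4e-04, 5 of 6 slides) and Gzmm fell (-3.93 ± 0.39, adjusted p = 3.1e-07). Gzmb (1.64 ± 0.91, adjusted p = 0.234, 5 of 6 slides) and Gzma (0.21 ± 0.57, adjusted p = 0.819, 4 of 6 slides) were not called. Immediate early and stress genes rose in 21 of 36, with 23 in either direction adjusted over the list alone (median 1.64, adjusted p = 3.8e-14; adjusted p = 0.0839 with an estimated correlation). Fosb (6.62 ± 0.67, adjusted p = 4.8e-07) and Hspb1, a small heat shock protein (5.78 ± 0.99, adjusted p = 3.6e-04, at least 12.5-fold higher), were among them.

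Paneth cells secrete antimicrobial peptides in intestinal crypts, and defensin genes rose in intestine Trm. Itln1, an intelectin (9.95 ± 0.92, adjusted p = 1.1e-07, at least 232-fold higher), and Mmp7, the protease that processes alpha-defensins (5.98 ± 0.67, adjusted p = 1.6e-06, at least 17.4-fold higher), rose with them. Of the defensin genes, Defa42 rose (10.19 ± 0.91, adjusted p = 7.0e-08, at least 318-fold higher), and its probe can also bind transcripts of its paralogs. Paneth, goblet and enteroendocrine markers rose in 9 of 10, with 9 adjusted over the list alone (median 5.19, adjusted p = 6.9e-13; adjusted p = 0.0839 with an estimated correlation). Enterocyte and gut epithelial markers rose in 10 of 14, with 12 adjusted over the list alone (median 3.20, adjusted p = 1.6e-12; adjusted p = 0.0873 with an estimated correlation), including the lectin gene Reg3g (7.20 ± 0.55, adjusted p = 4.0e-08, at least 33.9-fold higher). Fibroblast and smooth muscle markers rose in 10 of 12, with 12 adjusted over the list alone (median 3.74, adjusted p = 6.0e-09, 5 of 6 slides; adjusted p = 0.181 with an estimated correlation). B cell and plasma cell markers rose in 8 of 14, with 10 in either direction adjusted over the list alone (median 2.08, adjusted p = 1.2e-05; adjusted p = 0.340 with an estimated correlation). Jchain, which joins secreted immunoglobulin, rose (7.66 ± 0.68, adjusted p = 7.0e-08). In intestine Trm 698 genes were higher than in Tem and 828 lower, 1526 in all, with 1332 when the slide was a block and 1050 of one direction on all 6 slides. Probes never above background were 0.70 higher (log2 median), and 348 of the 698 higher genes were above background on every intestine Trm array. Scaling over all probes gave 598 higher and 1368 lower.

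Lung endothelial and stromal markers in intestine Trm rose in 11 of 18, with 12 adjusted over the list alone (median 2.82, adjusted p = 1.4e-08; adjusted p = 0.211 with an estimated correlation). Liver endothelial and Kupffer cell markers rose in 3 of 11, with 4 adjusted over the list alone (median 1.03, adjusted p = 0.00402, 5 of 6 slides; adjusted p = 0.480 with an estimated correlation). Hepatocyte markers rose in 1 of 22, with 1 adjusted over the list alone (median 0.71, adjusted p = 0.0149, 5 of 6 slides; adjusted p = 0.788 with an estimated correlation). Lung epithelial markers rose in 2 of 14, with 2 adjusted over the list alone (median 0.90, adjusted p = 0.0372; adjusted p = 0.735 with an estimated correlation). Probes never above background were 0.70 higher in intestine Trm than in Tem (log2 median), and the hepatocyte median lay at that level. The shifts of hepatocyte and lung epithelial markers ended under quantile normalization, with the deposited values and with normexp. That of lung epithelial markers also ended without liver Trm 3 and Tem 3, and without liver Trm 3, intestine Trm 2 or Tem 2 or 6 (highest adjusted p 0.0831). Proliferation genes fell in 3 of 23 in intestine Trm, with 2 adjusted over the list alone (median -0.67, adjusted p = 0.0105; adjusted p = 0.753 with an estimated correlation). Without Tem 2 that shift was not called (highest adjusted p 0.0918).

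Several regulators in intestine Trm were called by a narrow margin. Prdm1, which encodes Blimp-1, rose (1.99 ± 0.69, adjusted p = 0.0479). Quantile normalization, the deposited values and normexp ended that call, as did leaving out intestine Trm 2, 3, 4, 5 or 6 or Tem 1, 3, 4, 5 or 6 (highest adjusted p 0.122). Ccr9, a receptor for gut homing, rose (1.34 ± 0.43, adjusted p = 0.0322). Scaling over all probes ended that call, as did leaving out intestine Trm 1, 3, 4 or 5 or Tem 2, 3 or 5 (highest adjusted p 0.0813). Eomes, a T-box factor, fell (-2.26 ± 0.74, adjusted p = 0.0368). Quantile normalization and the deposited values ended that call, as did leaving out intestine Trm 2, 3, 4 or 6 or Tem 1 or 2 (highest adjusted p 0.0936). Tcf7, a factor of naive and central memory cells, fell (-1.22 ± 0.38, adjusted p = 0.0270). The slide as a block ended that call, as did leaving out intestine Trm 2 or 6 or Tem 1, 3, 4 or 6 (highest adjusted p 0.0683).

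**Figure D2:**
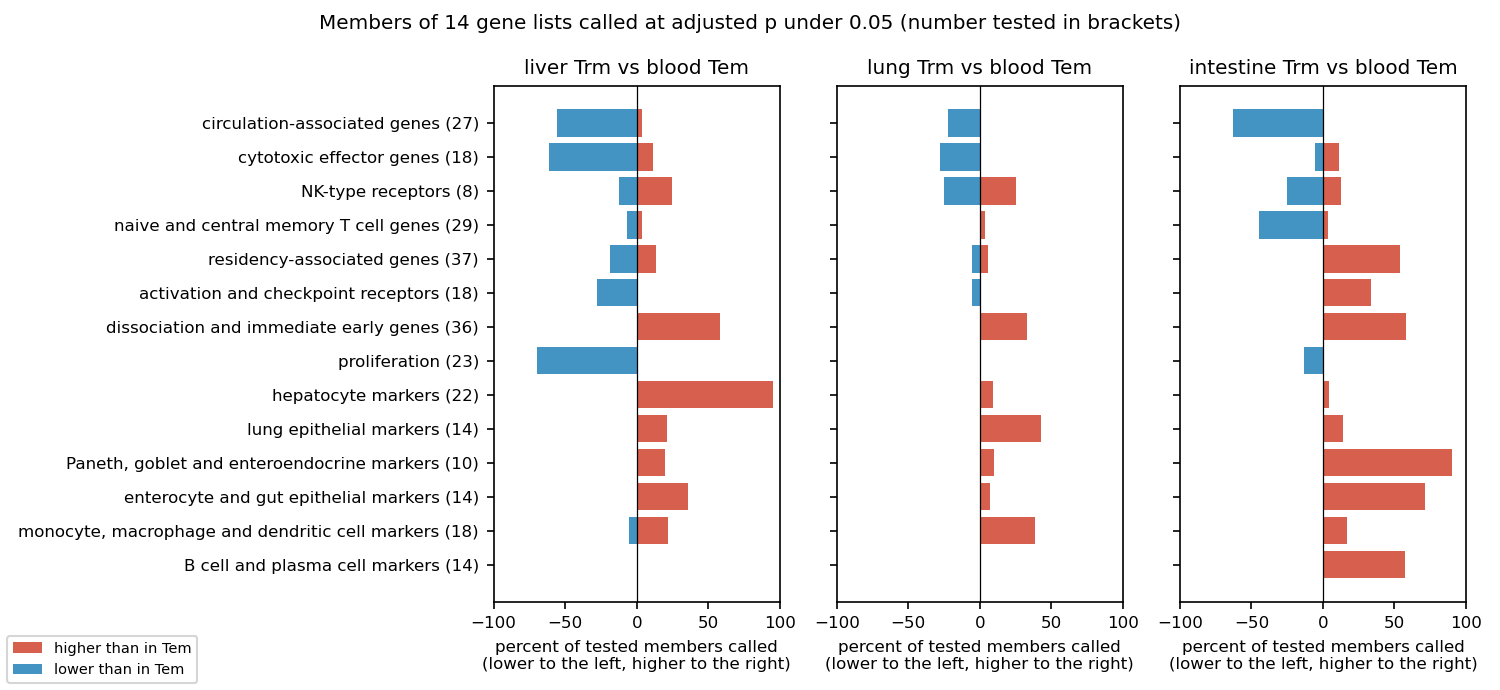
Percent of the tested members of 14 gene lists called higher (right, red) or lower (left, blue) than in blood Tem at an adjusted p under 0.05, for each Trm population, with the number of members tested in brackets. Circulation-associated genes were lower in all 3 populations (15, 6 and 17 of 27 members), and residency-associated genes were higher in intestine Trm (20 of 37).

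Genes called in the same direction in all 3 Trm populations numbered 114, 77 higher and 37 lower than in Tem. Among the lower ones, Cx3cr1 differed by -5.51, -5.43 and -4.72 in liver, lung and intestine Trm, and Klrg1 by -4.87, -5.94 and -3.92. The granzyme gene Gzmm was also lower (-2.83, -2.74 and -3.93). The higher ones included the transcription factor gene Egr2 (3.82, 4.59 and 3.60) and the transferrin gene Trf (8.79, 5.59 and 5.10). Sparc, a matrix protein of stromal and endothelial cells, was higher as well (5.61, 5.36 and 5.54). Independent lists of the same sizes would share 4.36 genes. In 100 simulations of unchanged groups 0 genes were shared. No gene was changed in them, so they do not show how much sharing the common Tem arrays add among called genes. Correlations of the differences were 0.47 (liver and lung), 0.64 (liver and intestine) and 0.49 (lung and intestine), against simulated medians of 0.53, 0.49 and 0.54. Covariances were 0.55, 1.00 and 0.50, above the highest simulated (0.37, 0.53 and 0.47). The comparisons share the Tem arrays, and over 90 splits that gave each Trm population its own Tem arrays a median of 18 genes was shared (10 to 29). Each population then had only a pair of Tem arrays, which lowers the number of genes that can be called. With the slide as a block 92 genes were shared, and 66 without liver Trm 3 and Tem 3.

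Genes that set 1 Trm population apart from Tem and from both other Trm populations numbered 611. Liver Trm had 161 higher, with the hepatocyte genes Serpina1c, Ahsg and Alb among them, and 207 lower. The galectin gene Lgals3 was among the lower (-2.26 ± 0.47, adjusted p = 0.00207 against Tem). Lung Trm had 20 higher, with Chil3, Ear2 and the surfactant genes Sftpc and Sftpa1 among them, and 6 lower. Intestine Trm had 182 higher, among them defensin genes, Itln1, Jchain and Reg3g, and 35 lower, among them Dapl1 and S100a4. Of the higher genes, 14 of 161 in liver Trm were also above whole liver and 120 below it. In lung Trm 5 of 20 were above whole lung and 3 below, and in intestine Trm 65 of 182 above whole intestine and 27 below. Simulations of unchanged groups, in which no gene was changed, gave 0. With the slide as a block there were 437, and 357, 366 and 955 without liver Trm 6, 5 and 2. Quantile normalization, the deposited values and scaling over all probes gave 1229, 1238 and 951. Liver Trm genes, 368 in all, numbered 736, 178, 155 and 161 without liver Trm 2, 3, 5 and 6 and 245 without lung Trm 2. Lung Trm genes, 26 in all, numbered 15 without liver Trm 6, 14, 45 and 40 without lung Trm 2, 4 and 5 and 76 without Tem 3.

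Hepatocyte genes were lower in lung Trm than in liver Trm, 21 of 22, with 21 adjusted over the list alone (median -5.27, adjusted p = 1.3e-30; adjusted p = 0.0839 with an estimated correlation), including Alb (-8.27 ± 0.60, adjusted p = 2.6e-09, at least 73.4-fold lower). Liver endothelial and Kupffer cell markers were lower in 6 of 11, with 8 adjusted over the list alone (median -2.68, adjusted p = 7.2e-08; adjusted p = 0.160 with an estimated correlation). Chil3 (6.51 ± 0.79, adjusted p = 7.6e-06) and Ear2 (5.73 ± 0.67, adjusted p = 5.1e-06, at least 13.4-fold higher) were higher in lung Trm. The T-box factor gene Tbx21 was lower (-2.39 ± 0.51, adjusted p = 0.00441), and Lgals3 was higher (2.32 ± 0.47, adjusted p = 0.00332). No shift was called of circulation-associated genes (median 0.04, adjusted p = 0.686, 0 adjusted over the list alone). Nor was one called of cytotoxic genes (median -0.39, adjusted p = 0.402, 0 adjusted over the list alone). The same held for residency-associated genes (median -0.43, adjusted p = 0.0968, 0 adjusted over the list alone). Of 1537 calls 802 were higher and 735 lower, with 937 when the slide was a block and 1210 of one direction on all 5 shared slides. Probes never above background differed by -1.09 (log2 median). Quantile normalization gave 2162 higher and 1221 lower, the deposited values 2182 and 1222, normexp 190 and 1626, and scaling over all probes 2866 and 618. The count was 2836, 665, 443 and 442 without liver Trm 2, 3, 5 and 6. It was 793, 641, 700, 2474 and 749 without lung Trm 1, 2, 3, 5 and 6.

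Lung epithelial markers in lung Trm, against liver Trm, were higher in 6 of 14, with 8 adjusted over the list alone (median 2.58, adjusted p = 0.00991, 3 of 5 slides; adjusted p = 0.667 with an estimated correlation). Without liver Trm 2 (highest adjusted p 0.0517) and with scaling over all probes that shift was not called. Interferon-stimulated genes were higher in 6 and lower in 1 of 26, with 10 adjusted over the list alone (median 0.81, adjusted p = 0.0272, 4 of 5 slides; adjusted p = 0.675 with an estimated correlation), a shift not called with scaling over all probes or without lung Trm 6 (highest adjusted p 0.0734). No member of the enterocyte and gut epithelial list was called, 0 adjusted over the list alone, while the list was lower in lung Trm (median -1.09, adjusted p = 0.0260, 4 of 5 slides; adjusted p = 0.675 with an estimated correlation). That shift ended under quantile normalization, with the deposited values, with normexp, without liver Trm 3 and Tem 3, and without liver Trm 3 alone (highest adjusted p 0.0690). Probes never above background differed by the same -1.09 (log2 median), so the shift cannot be told apart from a difference in background. Of B cell and plasma cell markers none was called either, 0 adjusted over the list alone, with a list shift down (median -0.96, adjusted p = 0.0304, 3 of 5 slides; adjusted p = 0.675 with an estimated correlation). It ended with normexp, without liver Trm 3 and Tem 3, and without liver Trm 5 or 6 or Tem 3 alone (highest adjusted p 0.117). The median of this list also lay near that of the probes never above background.

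Cytotoxic genes were higher in intestine Trm than in liver Trm in 7 of 18, with 12 in either direction adjusted over the list alone (median 1.30, adjusted p = 4.0e-04; adjusted p = 0.281 with an estimated correlation). Gzmb (5.28 ± 0.96, adjusted p = 7.8e-04, 4 of 5 slides) and Ccl4 (4.08 ± 0.53, adjusted p = 1.4e-05) were among them. Residency-associated genes were higher in 16 of 37, with 19 adjusted over the list alone (median 1.27, adjusted p = 1.8e-07; adjusted p = 0.181 with an estimated correlation). Litaf (3.78 ± 0.48, adjusted p = 1.1e-05) and Cish, a suppressor of cytokine signalling (2.95 ± 0.52, adjusted p = 6.5e-04), were among them. Activation and checkpoint receptors were higher in 10 of 18, with 11 in either direction adjusted over the list alone (median 1.55, adjusted p = 4.0e-04; adjusted p = 0.294 with an estimated correlation). Naive and central memory genes were lower in 7 of 29, with 12 adjusted over the list alone (median -0.67, adjusted p = 2.0e-06, 4 of 5 slides; adjusted p = 0.340 with an estimated correlation), including Dapl1 (-3.40 ± 0.76, adjusted p = 0.00462). Klf2 was lower (-1.23 ± 0.27, adjusted p = 0.00396), and the adhesion receptor gene Cd44 was higher (2.05 ± 0.27, adjusted p = 2.0e-05). Paneth, goblet and enteroendocrine markers were higher in 7 of 10, with 7 adjusted over the list alone (median 3.86, adjusted p = 6.5e-07; adjusted p = 0.205 with an estimated correlation). Hepatocyte markers were lower in 20 of 22, with 21 adjusted over the list alone (median -5.10, adjusted p = 6.3e-35; adjusted p = 0.0797 with an estimated correlation). Of 1010 calls 765 were higher and 245 lower, with 786 when the slide was a block and 672 of one direction on all 5 shared slides. Quantile normalization gave 948 higher and 707 lower, the deposited values 964 and 710, and normexp 343 and 266. The count was 640 without liver Trm 6 and 670 without liver Trm 5.

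Circulation-associated genes in intestine Trm, against liver Trm, were lower in 7 and higher in 1 of 27, with 10 adjusted over the list alone (median -0.53, adjusted p = 0.00298; adjusted p = 0.187 with an estimated correlation). Liver endothelial and Kupffer cell markers were lower in 7 of 11, with 8 adjusted over the list alone (median -2.30, adjusted p = 7.2e-08; adjusted p = 0.160 with an estimated correlation). Neutrophil and mast cell markers were lower in 3 of 9, with 7 in either direction adjusted over the list alone (median -2.22, adjusted p = 0.00154; adjusted p = 0.299 with an estimated correlation). Enterocyte and gut epithelial markers were higher in 4 of 14, with 6 adjusted over the list alone (median 1.23, adjusted p = 2.1e-04, 4 of 5 slides; adjusted p = 0.426 with an estimated correlation). Fibroblast and smooth muscle markers were higher in 3 of 12, with 3 adjusted over the list alone (median 2.25, adjusted p = 0.0112, 4 of 5 slides; adjusted p = 0.661 with an estimated correlation). Without liver Trm 1 or intestine Trm 2 or 4 that shift was not called (highest adjusted p 0.121). B cell and plasma cell markers were higher in 3 of 14, with 4 in either direction adjusted over the list alone (median 1.14, adjusted p = 0.0242, 3 of 5 slides; adjusted p = 0.675 with an estimated correlation). Their shift ended without liver Trm 1 or 2 or intestine Trm 2 or 6 (highest adjusted p 0.215). Proliferation genes were higher in 1 of 23, with 1 adjusted over the list alone (median 0.78, adjusted p = 0.0295; adjusted p = 0.804 with an estimated correlation). That shift ended without liver Trm 1 or 2 or intestine Trm 1 or 5 (highest adjusted p 0.148).

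Gzmb (6.53 ± 0.91, adjusted p = 5.7e-05) and Gzma (4.01 ± 0.57, adjusted p = 7.0e-05) were higher in intestine Trm than in lung Trm. Cytotoxic genes were higher in 8 of 18, with 11 in either direction adjusted over the list alone (median 1.26, adjusted p = 1.0e-06; adjusted p = 0.137 with an estimated correlation). Residency-associated genes were higher in 21 of 37, with 27 in either direction adjusted over the list alone (medians per slide 0.71 to 2.35, adjusted p = 3.8e-14; adjusted p = 0.0797 with an estimated correlation). Ahr (4.04 ± 0.59, adjusted p = 8.8e-05) and P2rx7 (3.74 ± 0.66, adjusted p = 6.4e-04) were among them. Activation and checkpoint receptors were higher in 8 and lower in 1 of 18, with 12 adjusted over the list alone (median 1.20, adjusted p = 3.2e-05; adjusted p = 0.205 with an estimated correlation). The inhibitory receptor genes Tigit (3.74 ± 0.82, adjusted p = 0.00495) and Ctla4 (3.02 ± 0.48, adjusted p = 2.3e-04) were higher, as was Prdm1 (3.14 ± 0.69, adjusted p = 0.00472, at least 3.21-fold higher). Naive and central memory genes were lower in 12 of 29, with 16 adjusted over the list alone (median -1.19, adjusted p = 5.1e-09; adjusted p = 0.205 with an estimated correlation). Lef1, a partner of beta-catenin in transcription, was among them (-2.77 ± 0.61, adjusted p = 0.00478). Paneth, goblet and enteroendocrine markers were higher in 9 of 10, with 10 adjusted over the list alone (median 3.93, adjusted p = 6.8e-12; adjusted p = 0.0839 with an estimated correlation). Lung epithelial markers were lower in 6 and higher in 1 of 14, with 11 adjusted over the list alone (median -2.52, adjusted p = 2.1e-04, 5 of 6 slides; adjusted p = 0.458 with an estimated correlation). Of 819 calls 452 were higher and 367 lower, with 689 when the slide was a block and 582 of one direction on all 6 slides. Quantile normalization gave 374 higher and 724 lower, the deposited values 369 and 720, normexp 535 and 263, and scaling over all probes 329 and 617. The count was 511 without lung Trm 3, 527 without lung Trm 2 and 1335 without liver Trm 3 and Tem 3.

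Circulation-associated genes in intestine Trm, against lung Trm, were lower in 5 and higher in 1 of 27, with 9 adjusted over the list alone (median -0.29, adjusted p = 0.0107, 4 of 6 slides; adjusted p = 0.273 with an estimated correlation). Enterocyte and gut epithelial markers were higher in 9 of 14, with 11 adjusted over the list alone (median 2.44, adjusted p = 6.0e-10; adjusted p = 0.143 with an estimated correlation). Fibroblast and smooth muscle markers were higher in 7 of 12, with 10 adjusted over the list alone (median 3.32, adjusted p = 8.3e-07; adjusted p = 0.273 with an estimated correlation). B cell and plasma cell markers were higher in 5 of 14, with 8 adjusted over the list alone (median 2.00, adjusted p = 1.1e-06; adjusted p = 0.279 with an estimated correlation). Lung endothelial and stromal markers were higher in 5 of 18, with 7 adjusted over the list alone (median 0.46, adjusted p = 0.0192, 4 of 6 slides; adjusted p = 0.675 with an estimated correlation). That shift ended without lung Trm 4 or 6 or intestine Trm 2, 3 or 4 (highest adjusted p 0.446). Probes never above background were also 0.46 higher in intestine Trm (log2 median), so the shift cannot be told apart from a difference in background. Neutrophil and mast cell markers were lower in 4 of 9, with 7 in either direction adjusted over the list alone (median -1.77, adjusted p = 0.0127, 5 of 6 slides; adjusted p = 0.438 with an estimated correlation), a shift not called without lung Trm 1 (highest adjusted p 0.0541). Monocyte, macrophage and dendritic cell markers were lower in 5 and higher in 1 of 18, with 6 adjusted over the list alone (median -0.40, adjusted p = 0.0101, 5 of 6 slides; adjusted p = 0.480 with an estimated correlation), a shift not called without intestine Trm 5 (highest adjusted p 0.0788).

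Liver Trm held more than whole liver of Ccr7, the lymph node homing receptor (9.73 ± 0.81, adjusted p = 7.4e-11, at least 192-fold higher), and Cd8b1 (6.47 ± 0.55, adjusted p = 8.5e-11, at least 18.6-fold higher). It held more of Cd69 (5.16 ± 0.59, adjusted p = 3.2e-08, at least 7.23-fold higher) and less of Apob, an apolipoprotein (-6.85 ± 0.49, adjusted p = 4.6e-12, at least 33.4-fold lower). Lung Trm held more than whole lung of the T cell receptor chain Cd3g (8.28 ± 0.62, adjusted p = 9.8e-12, at least 80.8-fold higher) and Tcf7 (6.86 ± 0.65, adjusted p = 5.3e-10, at least 29.3-fold higher). Bmp5, a growth factor, was lower in it (-8.21 ± 1.28, adjusted p = 3.4e-06, at least 77.1-fold lower). Intestine Trm held more than whole intestine of Ccr7 (9.73 ± 0.79, adjusted p = 5.2e-12, at least 199-fold higher) and Gzmb (4.36 ± 1.02, adjusted p = 9.5e-04), and less of Lct, the lactase of enterocytes (-9.06 ± 0.62, adjusted p = 6.5e-14, at least 169-fold lower). Blood Tem held more of Cd8b1 (6.50 ± 0.53, adjusted p = 4.4e-10) and S1pr1 (4.98 ± 0.55, adjusted p = 7.2e-08) than whole PBMC. Alas2, the first enzyme of heme synthesis in red cells, was lower in Tem (-6.38 ± 0.79, adjusted p = 5.4e-07).

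Of 10635 genes 3433 were called between liver Trm and whole liver, 907 higher in Trm and 2526 lower. For lung Trm there were 4419 (1673 and 2746), for intestine Trm 3384 (1243 and 2141) and for Tem 5874 (4667 and 1207). Sorted cells and whole organs lay on different slides scanned in different sessions, so slide and group cannot be told apart. A fit with slide as a random block gave 3435, 4418, 3386 and 5877 calls. For liver, quantile normalization gave 1409 higher and 2101 lower, the deposited values 1406 and 2100, normexp 1221 and 2123, and scaling over all probes 1443 and 1930. For blood the same settings gave 3937 and 2438, 3937 and 2438, 3810 and 1963, and 3615 and 3012. The blood count was 2952 without whole PBMC 1, and 3130 without the doubted arrays whole PBMC 1, whole liver 2, liver Trm 3 and Tem 3.

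**Figure D3:**
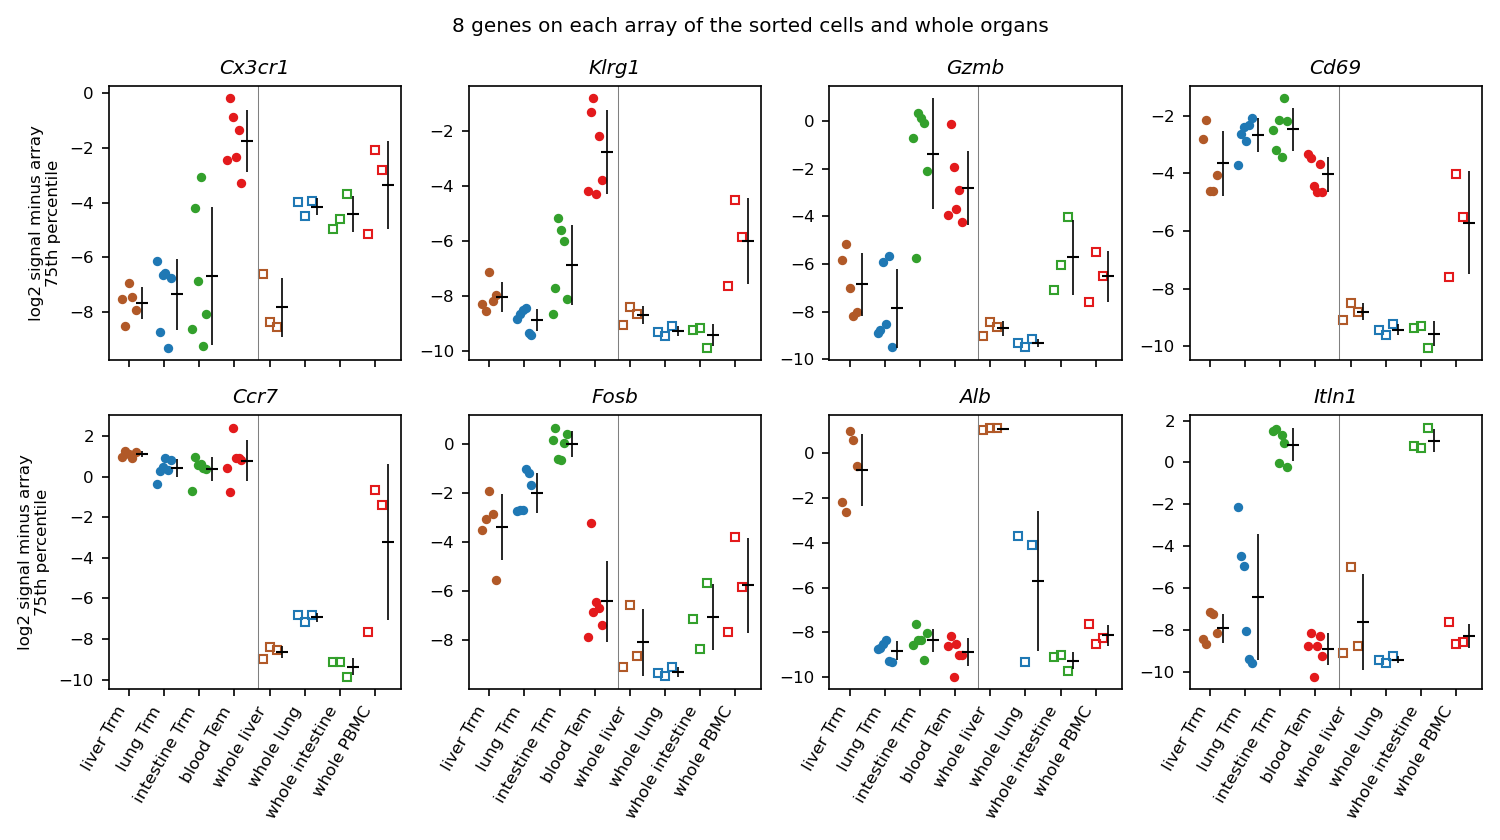
Log2 signal minus the 75th percentile of each array for 8 genes, 1 point per array (filled circles, sorted cells; open squares, whole organs and PBMC), with the mean and SD of each group beside its points. Cx3cr1 and Klrg1 were called lower than in Tem in the 3 Trm populations, and Cd69 higher in intestine Trm.

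Genes of a whole organ were followed in the sorted cells with the 50 genes highest in each organ relative to whole PBMC. In liver Trm the whole-liver genes were higher than in Tem by a log2 median of 5.68, 50 of 50 called, and lay at -3.18 relative to whole liver. Their medians in lung and intestine Trm were 0.07 and 0.52. Whole-lung genes had medians of 2.44 in lung Trm (17 called), 1.92 in liver Trm (18 called) and 2.60 in intestine Trm (29 called). In lung Trm they lay at -5.21 relative to whole lung. Whole-intestine genes had medians of 2.44 in intestine Trm (32 called), 0.96 in liver Trm (16 called) and 0.09 in lung Trm (3 called). In intestine Trm they lay at -6.83 relative to whole intestine. Camera called the shift of each organ's genes in its own Trm with an estimated correlation (adjusted p = 0.00416, 0.0156 and 0.0132 for liver, lung and intestine). Of all genes higher than in Tem, 62 of 1288 in liver Trm, 58 of 181 in lung Trm and 203 of 698 in intestine Trm were above the whole organ. Below it were 315, 35 and 163.

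**Figure D4:**
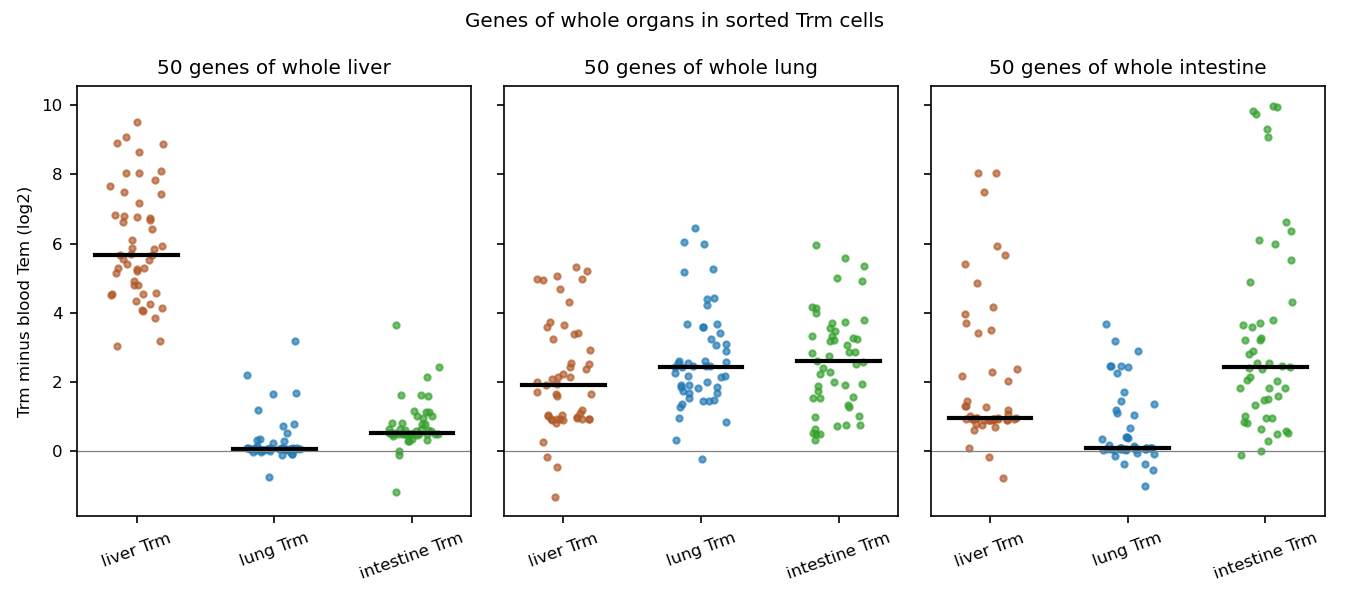
Log2 difference between each Trm population and blood Tem for the 50 genes highest in whole liver, whole lung and whole intestine relative to whole PBMC, 1 point per gene, with the median as a bar. Medians were 5.68 for whole-liver genes in liver Trm and 1.92, 2.44 and 2.60 for whole-lung genes in liver, lung and intestine Trm.

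Scaling also moved the median over all genes, given here as log2 against the main scaling. Quantile normalization and the deposited values each moved it by -0.12 in intestine Trm against Tem, 0.17 in lung against liver Trm and -0.21 in intestine against lung Trm. Both moved it by 0.33 in liver Trm against whole liver and -0.42 in Tem against whole PBMC. Normexp moved it by 0.46 and 0.14 in liver and intestine Trm against Tem, -0.40 in lung against liver Trm and -0.26 in intestine against liver Trm. For liver, intestine and blood against the whole organs normexp moved it by 0.31, 0.12 and -0.71. Scaling over all probes moved it by -0.47 and -0.27 in liver and intestine Trm against Tem. Among Trm populations that shift was 0.45 (lung against liver), 0.20 (intestine against liver) and -0.24 (intestine against lung). Against whole liver, whole lung and whole PBMC it was 0.41, 0.14 and -0.62.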

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

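Both patterns weighed here were chosen, and their tests written, after the results were seen; the rules that picked out single arrays, opposite calls and unnamed probes were set beforehand.

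Genes of an organ were higher in the Trm of that organ than in blood Tem, among them whole-liver genes in liver Trm and Paneth cell genes in intestine Trm. Whole-lung genes were not particular to lung Trm. Their medians against Tem were 2.44 in lung, 1.92 in liver and 2.60 in intestine Trm. Background or scaling of the arrays is argued against for liver, since the lowest median of the 50 whole-liver genes over the other scalings and corrections and without the doubted arrays was 3.64. Whole-intestine RNA carried over at 1 dilution is argued against, since the 32 whole-intestine genes above Tem lay from -8.10 to -0.19 against whole intestine, with an SD of 2.37 after a line on their level there, against 0.82 for the SE of 1 gene. Liver RNA or liver cells carried over cannot be told apart from uptake of such RNA or expression of these genes by the T cells, which was not tested. The whole-liver genes were 5.31 higher in liver Trm than in lung and intestine Trm, which restates the pattern, and whether they lay at 1 dilution of whole liver was not settled (SD 1.36 over the genes, against 0.73 for the SE of 1 gene). For intestine Trm, Paneth cells or their RNA carried over cannot be told apart from these either: the 4 Paneth genes among the 10 tested members of their list (Lyz1, Ang4, Mmp7 and Itln1) were above Tem and within 1 log2 of whole intestine, but they were told from the other 6, goblet and other secretory markers, after the results were seen.

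Immediate early genes were higher in the 3 Trm populations than in blood Tem. For whole-organ RNA carried over at 1 dilution, these genes were compared with the 50 genes of each organ, both relative to the whole organ. The members above Tem stood 4.30 ± 0.67 (SE) above the 50 genes for liver, 8.07 ± 1.04 for lung and 9.32 ± 0.80 for intestine. Over all 36 members tested the values were 4.58, 6.84 and 8.73. That gap cannot decide, because the 50 genes were picked as highest in the organ and the typical gene also stood far above them. Relative to the whole organ the median over all genes was -0.33, 0.09 and -0.01, against -3.18, -5.21 and -6.83 for the 50 genes. Of 21, 12 and 21 members above Tem in liver, lung and intestine, 8, 9 and 15 were called above the whole organ, 1 (Nr4a2), 0 and 1 (Klf4) below it, and 12, 3 and 5 neither. Sorted cells and whole organs lay on different slides scanned in different sessions. Members above both Tem and the whole organ exceed what a mixture of both would give. That argues against carried-over whole-organ RNA for those members, unless slide or session raised them. For the other members it was not settled. RNA of single cell types rich in these genes was not tested. Dissociation of the organs cannot be told apart from residence, because every Trm sample was dissociated and no Tem sample was. Whole organs stood at most 0.22 above whole PBMC in these genes, but they hold other cells, and the labels do not say that they were otherwise handled like the sorted cells.

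Single arrays far from the others of their group made up 15 of 68 tests, where chance picks out about 1 in 20 groups. The tests are not independent, since most of the 15 are the same array, Tem 3. Tem 3 was the lowest of its group in markers of hepatocytes (-8.73), liver endothelial and Kupffer cells (-9.06), lung epithelium (-7.99), lung endothelium and stroma (-8.55), enterocytes (-8.71), Paneth and goblet cells (-9.53) and fibroblasts (-8.81), and in its log2 negative control signal (9.82). The other Tem arrays stood at 12.17 to 12.51 in that signal, so the low marker values of Tem 3 cannot be told apart from its low background. Liver Trm 1 was lowest in liver endothelial and Kupffer cell markers (-5.36), intestine Trm 2 was highest in lung epithelial markers (-3.45) and Tem 2 lowest in naive and central memory genes (-4.41). Liver Trm 3 had 12.2% of probes well above background and intestine Trm 5 had 35.5%, each far from its group. Lung Trm 5 was lowest in its log2 negative control signal (11.78) and its log2 75th percentile (10.24).

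Some genes moved in opposite directions against Tem in 2 Trm populations, with the difference between the populations also called. Lower in liver and higher in intestine Trm were 10 genes, among them the chemokine gene Ccl4, the exonuclease gene Isg20 and the adenosine receptor gene Adora2a. Cd9, a tetraspanin, was the 1 gene lower in liver and higher in lung Trm. Adora2a and Casp4, an inflammatory caspase, were the 2 genes lower in lung and higher in intestine Trm. Probes without a gene name, which no comparison used, were called against Tem in 871 of 2950 cases (29.5%) for liver Trm, 123 (4.17%) for lung Trm and 331 (11.2%) for intestine Trm. Among named genes the shares were 40.3%, 3.13% and 17.7%.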

How the results depend on the processing

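Scaling over all probes and leaving out the doubted arrays liver Trm 3, Tem 3, whole liver 2 and whole PBMC 1 were chosen after seeing the data. No called named gene or list turned direction, 20 uncalled values of named genes did, and the cause of these and the moves below was not tested. The larger of the higher and lower counts changed sides for liver and intestine Trm against Tem and lung-liver with normexp and with no filter on dim probes. It did so with array weights for lung Trm against Tem, intestine-lung and lung and intestine Trm against the whole organ, and for intestine-lung under quantile normalization, with the deposited values and scaling over all probes. For lung-liver it also did so with the replicate block, a 2-fold minimum or only the 2 groups, for lung-liver and Tem against PBMC without the doubted arrays, and when some single arrays were left out. Quantile normalization gave 3383 calls between lung and liver Trm, 1655 between intestine and liver Trm and 1229 genes specific to 1 Trm population, and the deposited values 3404, 1674 and 1238. Normexp gave 609 between intestine and liver Trm, and a fit of only the 2 groups gave 628. Scaling over all probes gave 3484 between lung and liver Trm and 951 specific genes. With no filter on dim probes there were 13973 calls for liver Trm against Tem, 10703 between lung and liver Trm, 618 between intestine and liver Trm and 534 between intestine and lung Trm. Array weights, whose estimation did not converge, gave 1582 for lung Trm against Tem, 4903, 3077 and 2664 for lung-liver, intestine-liver and intestine-lung, 6925, 7717 and 6800 for liver, lung and intestine Trm against the whole organ, and 329 shared and 3069 specific genes. Without the doubted arrays there were 1774 for liver Trm against Tem, 1335 between intestine and lung Trm, 3130 for Tem against PBMC and 66 shared genes. With an estimated correlation 3 of 78 list calls held, and 60 of the 78 held whichever array was left out. Leaving out 1 array at a time gave 2242 to 3875 calls for liver, 175 to 289 for lung and 1209 to 1429 for intestine Trm against Tem. It gave 442 to 2836 for lung-liver, 640 to 1360 for intestine-liver and 511 to 1190 for intestine-lung, 2882 to 3409, 3741 to 4523 and 2736 to 3358 against whole liver, lung and intestine, and 2952 to 5884 for Tem against PBMC. Shared genes ranged from 81 to 123 and specific genes from 357 to 955. Of 1006 values of named genes, 939 kept direction and side of the threshold under quantile normalization, 938 with the deposited values, 917 with normexp and 962 with scaling over all probes. Folds of genes never above background in a group are lower bounds, and in liver Trm 396 of 1288 higher genes were above background on all its arrays.

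The replicate block gave 937 calls between lung and liver Trm, against 1537 without it, and 242 genes specific to liver Trm, against 368, moved no other count by over 1.5 times, and kept 942 of the 1006 values of named genes. Samples of one replicate number share a slide. Over 33 pairs of samples with one number, the correlation of what was left after the group means was -0.362 to 0.436 (median -0.00852), against a median of 0.00166 for different numbers, and 2 of 23 arrays were closest to one of their own number, so the numbers were not taken to pair the samples.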

Other observations

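The tests of regrouped arrays were chosen after the results were seen, and the gene lists were fixed earlier.

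Genes of fatty acid uptake and oxidation rose in 8 and fell in 3 of 21 in liver Trm (11 adjusted over the list alone; median 0.63, adjusted p = 0.00471, 4 of 5 slides; adjusted p = 0.426 with an estimated correlation). They rose in 2 in lung Trm (3 adjusted over the list alone; median 0.26, adjusted p = 0.00306; adjusted p = 0.405 with an estimated correlation) and 6 in intestine Trm (8 adjusted over the list alone; median 1.13, adjusted p = 0.00477; adjusted p = 0.426 with an estimated correlation). Probes never above background were 1.33, 0.24 and 0.70 higher than in Tem in liver, lung and intestine Trm (log2 medians). The fatty acid median lay at that level in lung Trm and under it in liver Trm. Those 2 shifts cannot be told apart from a difference in background. Hepatocyte markers in liver Trm (median 6.19) and enterocyte markers in intestine Trm (median 3.20) were higher as well. So were lung epithelial (median 4.39) and monocyte, macrophage and dendritic cell markers (median 1.66) in lung Trm. No shift of glycolysis and lactate genes was called in any Trm population. Interferon-stimulated genes fell in 10 of 26 and rose in 2 in liver Trm (12 adjusted over the list alone; median -0.89, adjusted p = 0.192). T cell transcription factors rose in 10 and fell in 3 of 28 in intestine Trm (16 adjusted over the list alone; median 0.40, adjusted p = 0.0619). Natural killer type receptors, cytokine receptors, and genes of the TGF-beta, AHR and Notch pathways had no shift called in any Trm population against Tem. The same held for T cell identity genes, erythroid markers, genes of gamma-delta, MAIT and NKT cells, and genes of CD4 and regulatory T cells.

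Of 462 possible splits of the arrays, 100 were drawn for each comparison among sorted cells. For liver (3477 against 2263 in the highest other split), lung (270 against 16) and intestine Trm (1526 against 316) against Tem, 1 of 100 splits, the real one, was as large. The same held for intestine against lung Trm (819 against 580, 1 of 100). Other splits mix groups that differ, which adds the difference to their spread, and their median count was 0. The splits bear only on chance assignment of the arrays. Handling, slide or array quality that goes with a group is not excluded by them. For lung against liver Trm (1537) and intestine against liver Trm (1010), 2 of 100 splits were as large, the other reaching 2558 with liver Trm 2 exchanged for lung Trm 5, and 1586 with liver Trm 2 exchanged for intestine Trm 2. Against whole liver, lung and intestine and PBMC, 1 split of 56, 84, 84 and 84 was as large (3433 against 2170, 4419 against 1419, 3384 against 1199 and 5874 against 4191). Shared genes numbered 114 against 563 in the highest other split (2 of 100), and specific genes 611 against 7 (1 of 100). List shifts numbered 78 against 76 (1 of 100), with a median of 49 list shifts over the splits. Regrouped arrays thus also gave many list calls at the preset correlation, so those adjusted p-values overstate the evidence for single lists. Whole-organ genes had medians of 5.68 against 4.66 for liver (1 of 100), 2.44 against 2.57 for lung (3 of 100) and 2.44 against 2.18 for intestine (1 of 100).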
